A study of Homo sapiens with 4 samples.

How the data were processed

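RNA was measured in 4 libraries of T24, an established line of human bladder cancer cells. Per the labels, 2 libraries came from cells given a scramble control and 2 from cells made to overexpress miR-146a-5p. The study's description gives the means as transfection of a mimic, while the sample labels do not name it, and the text below uses the description's term. Groups and replicate numbers were taken from the labels. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. RNA was extracted with Trizol, and libraries were made from 1 ug of total RNA with a TruSeq RNA kit, per the labels' protocols.

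The submitters' processing notes name cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 without a version and the genome build hg19, with no role or order for each. The release of the gene annotation is not given in the sources used here. The deposited table holds 60623 genes with an estimated count per library, and 34.3% of the values in genes detected in all 4 libraries were not whole numbers. Which tool gave fractional values is not given in the sources used here, and fractional counts arise where reads are shared among genes or transcripts by a model, so genes with near-identical copies carry an added uncertainty. The table also holds TPM (transcript abundance scaled by length and library) per library and as a mean per group, made by the authors, which were not used for any test. The authors' fold change is a ratio of miR-146a-5p over scramble, and the authors' log2 fold change is its logarithm. The authors' p-value and adjusted p-value come from their DESeq2 comparison, per the file headers, and 34811 genes are listed there as not tested.

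Estimated counts were rounded to whole numbers before every test. Each library's total estimated count was between 20290055 and 22774090, and 14810 genes passed edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors, group as the only term, two-sided, and Benjamini-Hochberg adjustment with a threshold of 0.05. The replicate number was not used as a block, because the labels do not say that a number marks a shared culture, batch or day. DESeq2 1.42.0 with its default filtering (target 0.1) was an alternative test of the same counts. With a filtering target of 0.05, DESeq2 called 51 genes in place of 52. Log2 CPM used a prior count of 2. Standard errors of edgeR fold changes were derived from the F statistic.

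A total of 26 gene lists were drawn up from general knowledge before the data were examined. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with adjustment over the 24 lists that had at least 3 tested members, and again with an estimated correlation. The latter setting also rests on the few residual degrees of freedom of the libraries. Its larger p can therefore arise without correlation among members. Members past the threshold were counted over all genes and adjusted over the list alone. Matches to the miR-146a-5p seed (an 8-mer, a 7-mer matching positions 2 to 8, or a 7-mer matching positions 2 to 7 followed by A) were searched in the 3' UTR of the longest protein-coding transcript of each gene in GENCODE release 29 (GRCh38). Of the deposited gene identifiers, 58457 were in that annotation, and 12359 tested genes had a 3' UTR there. Genes with no annotated 3' UTR were left out of that comparison. The difference in median log2 fold change between genes with and without a match was compared with the same difference for 419 permutations of the seed match, which gives the permutation p of that comparison. Coordinates are 1-based, from GRCh38, by match to that annotation, and no coordinate of the authors' build was used.

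The rule for naming genes was fixed before the data were examined. It takes, among genes past the threshold with a mean of at least 1 CPM and with both miR-146a-5p libraries on the same side of both scramble libraries, the 10 with the largest increase and the 10 with the largest decrease. It adds IRAK1, TRAF6, EGFR, NUMB, SMAD4 and the miR-146a precursor gene or its host. It also adds up to 4 genes past the threshold per list (or up to 2 with the smallest p where there are none) and up to 6 genes past the threshold with an 8-mer match. Because edgeR put no gene past the threshold, the rule was applied to the DESeq2 test, a step chosen after the data were seen.

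The tests were checked on simulated data. Counts for the 14810 genes were drawn from the scramble means and the real library sizes, with 100 well-expressed genes changed 2-fold and 100 changed 4-fold. With the spread of all 4 libraries, edgeR recovered 0 of the 100 genes changed 2-fold and 0 of those changed 4-fold, with 0 false calls. In the same simulation DESeq2 recovered 7 of the 100 genes changed 2-fold and 77 of those changed 4-fold, and it also called 68 unchanged genes. With the spread of the 2 miR-146a-5p libraries, edgeR recovered 97 and 100, with 7 false calls. A simulated list of 30 genes shifted by 0.75 log2 units was recovered by camera at the wider spread, and 4 of 200 unchanged lists had a value under 0.05. Simulated genes varied independently and with the same spread in both groups. In the data the scramble pair varied more, and members of a list can move together. The simulated rates therefore need not hold for the data. In the seed test, a log2 shift of -0.2 was placed on each of 5 heptamers in turn, the seed match itself among them. The shifted heptamer was the lowest in 5 of 5 trials over 12359 genes. Fold changes varied independently in these trials. The shift was larger than the differences found in the data, and smaller ones were not tried in this test.

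Alternatives fixed before the data were examined were other scaling factors, no filter and a stricter filter of 50 counts in 2 libraries, DESeq2, limma-voom, a replicate block, leaving out each library, stricter thresholds, camera with an estimated correlation, fry, other 3' UTR definitions and site classes, and matched genes. Others were added after the data were seen, mostly because scramble replicate 2 stood apart. These were library quality weights, offsets for transcript GC content and length, tests of only the GC-rich or only the GC-poor genes, split at the median, a crossed pairing, DESeq2 without each library, permuted heptamers without CG, and seed matches with the GC and length offsets. Motifs of 7 bases in the 3' UTR were scanned on fold changes from which a polynomial of degree 3 in transcript and 3' UTR length and GC content and in mean expression had been removed in 5 held-out parts, with values clipped at 2, for the 16208 heptamers found in at least 50 genes.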

Results

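RNA abundance per gene was read from 4 sequencing libraries of T24 cells, a line established from a human bladder carcinoma, 2 transfected with a scramble control and 2 with a miR-146a-5p mimic, as the study's description calls it. Total estimated counts were 22388468 and 22774090 in scramble replicates 1 and 2, and 21544243 and 20290055 in miR-146a-5p replicates 1 and 2. Between 20515 and 21266 genes had a count above 0. Scramble replicate 2 stood apart, with a Pearson correlation across genes of 0.925 with scramble replicate 1, while the 2 miR-146a-5p libraries were correlated at 0.989.

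The design asks which transcripts change when miR-146a-5p is raised in bladder cancer cells. Changes of single genes below passed DESeq2, while edgeR called none. IRAK1, the interleukin-1 receptor-associated kinase and a textbook target of this microRNA, fell 5.59-fold, from 608 ± 154 CPM in scramble cells to 109 ± 0.187 CPM in miR-146a-5p cells (SD, n = 2 each, CPM being counts scaled by library total to a common depth). Its estimated counts were 11155 and 16314 in the scramble libraries against 2329 and 2217 with the mimic, and its log2 fold change was -2.50 ± 0.35 (SE) with an adjusted p of 5.03e-09 by DESeq2 and 0.728 by edgeR. CARD10, an adaptor that links receptors to NF-kB, fell 2.98-fold, from 82.3 ± 25.9 to 27.6 ± 2.50 CPM (DESeq2 adjusted p = 0.0262). TRAF6, the ubiquitin ligase that acts after IRAK1, had 16.04 ± 4.59 CPM in scramble and 9.34 ± 0.875 CPM in miR-146a-5p cells, below both scramble libraries in both replicates, and did not pass (DESeq2 adjusted p = 1.00). EGFR (594 ± 136 and 433 ± 30.4 CPM), NUMB (91.6 ± 3.49 and 85.8 ± 0.845 CPM) and SMAD4 (72.4 ± 21.9 and 77.1 ± 2.39 CPM) did not pass either, and the sign of SMAD4 differed without scramble replicate 2 and with GC and length offsets. The gene of the miR-146a precursor had 0 counts in all 4 libraries. Its host transcript MIR3142HG rose, from 24 and 9 counts to 179 and 194 (log2 fold change 3.58 ± 0.64, DESeq2 adjusted p = 2.71e-05). The sample labels name overexpression without its means, so these counts cannot be assigned to the cells' own gene rather than to transfected material. Of the 31 listed published targets, 28 were tested, 2 fell (IRAK1 and CARD10), 26 did not pass, and the list median was 0.02. The list as a whole was not called (camera adjusted p = 0.802).

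Among the genes with the largest increases, C3, the central complement component, rose 15.6-fold, from 9.53 ± 3.99 to 149 ± 6.90 CPM (SD, n = 2, DESeq2 adjusted p = 4.52e-15). CSF2, the cytokine GM-CSF, rose 15.5-fold, from 0.775 ± 0.147 to 11.99 ± 0.160 CPM. The neutrophil chemokines CXCL1 and CXCL8 rose 7.13-fold and 7.03-fold, to 750 ± 17.2 and 350 ± 2.38 CPM. The epithelial transcription factor ELF3 rose 6.55-fold, the mucin MUC5AC 7.90-fold, GOLGA7B 6.49-fold and the noncoding LINC02376 5.78-fold. CD69 had 2 and 0 counts in the scramble libraries against 38 and 45 with the mimic (DESeq2 adjusted p = 0.0112). Besides IRAK1 and CARD10, the genes that fell were TIMM17B, a subunit of the mitochondrial import machinery (3.25-fold), the noncoding LINC00707 (3.16-fold) and LINP1 (2.78-fold), SERPINB2, an inhibitor of plasminogen activators (3.14-fold), HMOX1, the haem oxygenase (2.56-fold), and ANKRD33B (2.33-fold). DESeq2 adjusted p-values for these 6 were between 0.0103 and 0.0331.

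**Figure D1:**
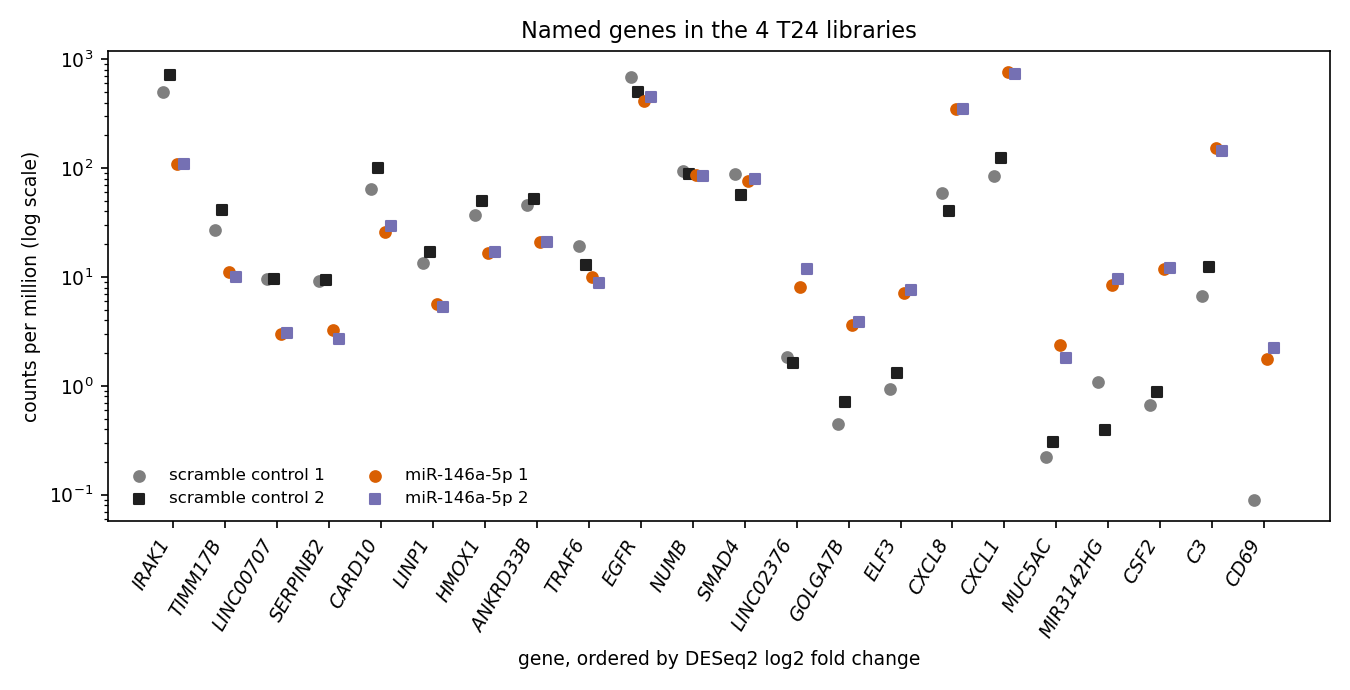
CPM (vertical axis, log scale) of the named genes in each of the 4 libraries, 1 point per library, ordered by DESeq2 log2 fold change. IRAK1 lies at 499 and 717 CPM in the scramble libraries and at 109 CPM in both miR-146a-5p libraries, and CD69 has no point for scramble replicate 2, where its count was 0.

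The number of genes called depended on the test. edgeR's quasi-likelihood test called 0 of 14810 genes, with 549 at an unadjusted p under 0.05 and a lowest adjusted p of 0.728. DESeq2 on the same counts called 52, of which 44 were higher and 8 lower with the mimic, and limma-voom called 0. The authors' deposited table also lists 52, with 44 higher and 8 lower, and all 52 were shared with the DESeq2 test here. In all 52 genes both miR-146a-5p libraries lay on the same side of both scramble libraries, which their selection by DESeq2 from these same libraries favours. Such a separation held for 5326 tested genes, 36.0% against 33.3% by chance. In simulated counts with the spread of these 4 libraries, edgeR recovered 0 of 100 genes changed 4-fold, and DESeq2 recovered 77 but also called 68 unchanged genes. That simulation gave both groups the same spread and let genes vary independently, unlike these libraries, so its rates need not hold here. Without scramble replicate 2 edgeR called 3343 genes (1550 higher, 1793 lower) and without scramble replicate 1 it called 8421, each with the lone scramble library assumed to vary like the miR-146a-5p pair. Without miR-146a-5p replicate 1 or 2 the counts were 12 and 8. DESeq2 called 1107 genes without scramble replicate 2, including 49 of the 52, 5349 without scramble replicate 1, and 2 without either miR-146a-5p library.

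The 2 scramble libraries differed more than 2-fold in 23.5% of genes, against 2.71% for the miR-146a-5p pair, whose common biological coefficient of variation was 0.0610. Scramble replicate 1 correlated with the miR-146a-5p libraries at 0.979 and 0.981, and scramble replicate 2 at 0.942 and 0.936. In the group of genes with the lowest transcript GC content, scramble replicate 2 was below scramble replicate 1 (median log2 difference -1.53), and in the group with the highest it was above (0.51). Neither group held the same library in duplicate, because the counts of each pair differed by more than sampling noise. The chi-square per degree of freedom was 179 for the scramble pair and 6.98 for the miR-146a-5p pair.

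**Figure D2:**
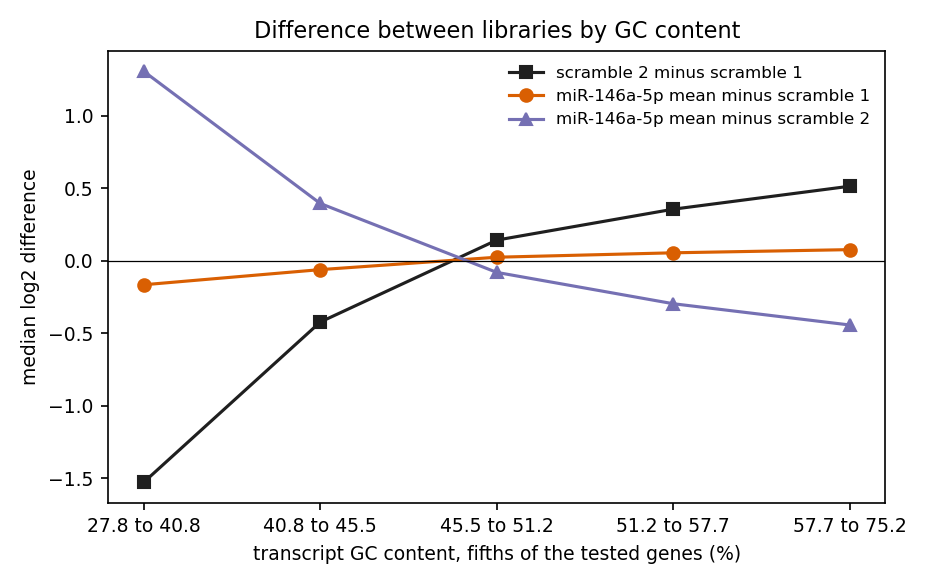
Median log2 difference between libraries (vertical axis) for 5 equal groups of the tested genes ordered by transcript GC content (horizontal axis, percent). Scramble 2 minus scramble 1 runs from -1.53 to 0.51, while the mean of the miR-146a-5p libraries minus scramble 1 runs from -0.17 to 0.08.

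In the list of genes that respond to the transcription factor NF-kB, 11 of 32 tested members rose by DESeq2 and 21 did not pass. Of the 32 tested members of a 37-gene list, 29 had a positive log2 fold change, with a median of 1.04, and 22 lay above both scramble libraries in both replicates, where chance gives 16.7% of genes. The list was called by camera (adjusted p = 2.07e-16), with an adjusted p = 0.438 with an estimated correlation. That estimated correlation was 0.213, above the preset 0.01, so members that move together may add to the larger value. DESeq2 called 0 members lower, and edgeR called 0 over all genes and 14 adjusted over the list alone. CSF2, CXCL1, CXCL8 and IL6 had the smallest adjusted p, and IL6, an acute-phase cytokine, rose 4.93-fold, from 5.83 ± 0.711 to 28.7 ± 2.53 CPM (DESeq2 adjusted p = 1.81e-07). The median of the list was 0.97 against scramble replicate 1 alone and 1.21 against scramble replicate 2 alone. CXCL1, CXCL2 and CXCL3 are close copies of one another, so their estimated counts may be shared among them. The receptors and kinases upstream of NF-kB were not called as a list (29 tested, median 0.07, camera adjusted p = 0.504), and IRAK1 was the 1 member called by DESeq2.

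Interferon-stimulated genes were the second list with a large shift. Of 35 tested members of a 40-gene list, 33 had a positive log2 fold change, 30 lay above both scramble libraries and 0 below both, and the median was 0.77. Members not tested were near the floor. Among them IFNB1 had 0 counts in every library and IFNL1 had 1 and 1 in scramble against 1 and 0 with the mimic. CXCL10 had 0 and 0 against 0 and 2, and CXCL11 had 2 and 1 against 0 and 3. Camera called the list (adjusted p = 2.50e-14), with an adjusted p = 0.279 with an estimated correlation. The estimated correlation was -0.027, below the preset 0.01, so correlation among members does not account for the larger value. No member was called over all genes by edgeR (7 at p under 0.05) or by DESeq2, and adjusted over the list alone edgeR called 0 and DESeq2 5. The members with the smallest edgeR p were CMPK2, an antiviral nucleotide kinase (0.311 ± 0.0666 and 1.86 ± 0.209 CPM), and OAS2, an oligoadenylate synthetase (9.51 ± 0.464 and 19.8 ± 0.285 CPM). The list median was 0.82 against scramble replicate 1 alone and 0.57 against scramble replicate 2 alone.

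Hypoxia and glycolysis genes were called higher (24 tested, median 0.59, camera adjusted p = 2.79e-05), with an adjusted p = 0.639 with an estimated correlation and 0.117 without scramble replicate 1. The estimated correlation of that list was 0.274, above the preset 0.01. The members with the smallest p were CA9, a carbonic anhydrase (0.752 ± 0.367 and 3.54 ± 0.221 CPM), and MXI1 (6.92 ± 0.149 and 12.6 ± 1.13 CPM), and neither was called. Mesenchymal genes were called higher (24 tested, median 0.30, camera adjusted p = 0.00449), with an adjusted p = 0.462 with an estimated correlation, 0.289 without scramble replicate 1 and 0.0733 without miR-146a-5p replicate 1. Its 2 members called by DESeq2 were FN1, fibronectin, which rose 3.73-fold from 1116 ± 176 to 4161 ± 32.4 CPM, and TAGLN, an actin-binding protein, which rose 3.58-fold. Epithelial genes were called higher as well (16 tested, median 0.39, camera adjusted p = 0.00449), with an adjusted p = 0.438 with an estimated correlation, 0.117 without scramble replicate 1 and 0.102 without scramble replicate 2. ELF3 was its 1 member called by DESeq2. The epithelial list has 24 members, and those not tested were near the floor. CDH1 was among them, with 0 and 2 counts in scramble against 0 and 1 with the mimic. Matrix genes and proteases were not called (32 tested, median 0.15, camera adjusted p = 0.242), but were at 0.0147 without scramble replicate 2 and at 0.0358 with GC and length trends removed, and its members FN1 and TNC, the matrix protein tenascin C (3.09-fold), rose by DESeq2. In the basal urothelial list 3 of 15 members were tested (median 0.38, camera adjusted p = 0.0318). The rest were near the floor, and KRT5 had 0 counts in every library. The adjusted p was 0.505 with an estimated correlation, and the call was lost without any 1 of the 4 libraries (0.167 to 0.564). KRT17 (0.353 ± 0.246 and 1.41 ± 0.148 CPM) and CD44 (917 ± 51.7 and 1193 ± 0.0945 CPM) were not called.

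The list of G2/M and mitosis genes was called higher by camera at the preset correlation, with no member called. It had 30 tested members, 18 above both scramble libraries, and a median of 0.28. Its camera adjusted p was 0.00623, and 0.438 with an estimated correlation (-0.032, below the preset 0.01). UBE2C (151 ± 24.4 and 205 ± 0.757 CPM) and TPX2 (620 ± 24.4 and 747 ± 11.5 CPM) had its smallest p, and the sign of TPX2 differed when only GC-poor genes were fitted. Mitochondrially encoded genes were called lower as a list, with no member called (13 tested, 12 below both scramble libraries, median -0.35, camera adjusted p = 9.00e-05). The adjusted p was 0.639 with an estimated correlation (0.455, above the preset 0.01). MT-CO1 was at 13487 ± 158 and 10588 ± 440 CPM, and MT-CO3 at 3429 ± 343 and 2511 ± 23.9 CPM. Cytosolic ribosomal protein genes were called lower (36 tested, median -0.18, camera adjusted p = 0.00749), with an adjusted p = 0.863 with an estimated correlation (0.882, above the preset 0.01). That list turned with the scramble library used. Its median was 0.07 against scramble replicate 1 alone and -0.38 against scramble replicate 2 alone, its direction reversed without scramble replicate 2 (0.118), and its call was lost without miR-146a-5p replicate 2 (0.262). RPS16 was at 563 ± 148 and 433 ± 43.1 CPM and RPL13 at 1704 ± 577 and 1285 ± 132 CPM.

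The other lists did not pass at 24 lists tested. Medians were -0.05 for G1/S and DNA replication genes (camera adjusted p = 0.686), 0.08 for p53 targets (0.941), 0.09 for apoptosis regulators (0.504), -0.07 for EGFR and MAPK output (0.802), 0.01 for adhesion and motility (0.802), 0.12 for the TGF-beta and SMAD pathway (0.363), -0.09 for the Notch pathway (0.805), -0.01 for cholesterol synthesis (0.566), 0.14 for the unfolded protein and integrated stress response (0.504) and -0.32 for 8 luminal urothelial markers (0.242). TGFA, a ligand of EGFR, rose 2.68-fold, from 11.5 ± 1.46 to 30.9 ± 2.88 CPM (DESeq2 adjusted p = 0.0169), and PMEPA1, a feedback inhibitor of TGF-beta signalling, rose 2.91-fold, from 18.6 ± 3.75 to 54.2 ± 2.98 CPM (adjusted p = 0.00619). KRT19 (37.2 ± 7.56 and 15.1 ± 1.05 CPM, DESeq2 adjusted p = 0.0681) and PPARG (43.2 ± 3.29 and 28.4 ± 0.445 CPM) were not called. The microRNA machinery was not called with 4 libraries (median -0.04, camera adjusted p = 0.551) but was lower without scramble replicate 2 (0.00468), and its median was -0.28 against scramble replicate 1 alone and 0.28 against scramble replicate 2 alone. Markers of other cell types were near the floor. Fibroblast, leukocyte and endothelial markers summed to between 18.6 and 27.2 CPM in each library, with 2, 3 and 0 members tested. The leukocyte list was not called (camera adjusted p = 0.504), and the fibroblast list reached 3 tested members only with a scramble library left out, with an adjusted p of 0.0127 without scramble replicate 2 and 0.329 without scramble replicate 1.

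**Figure D3:**
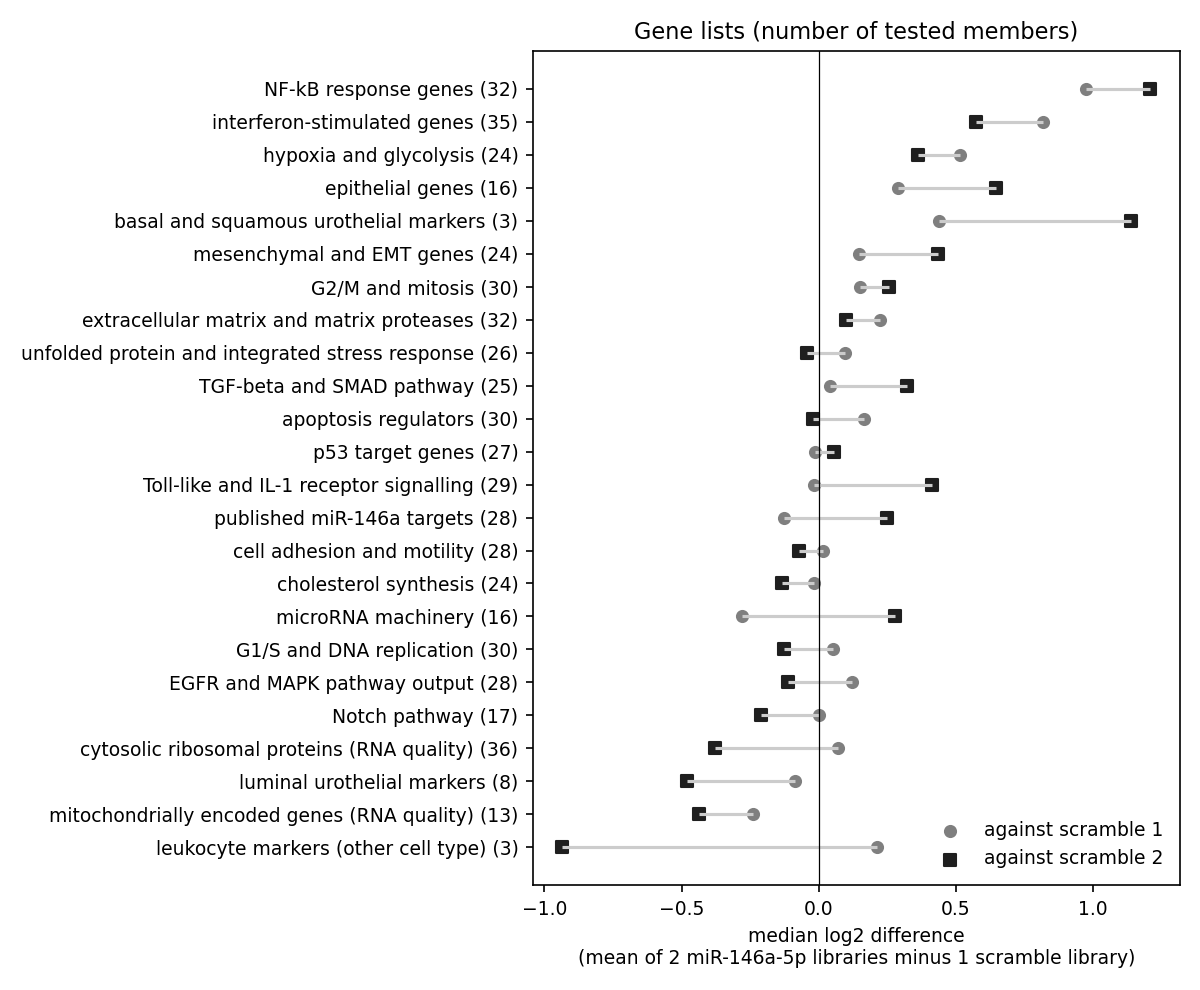
Median log2 difference of each gene list (horizontal axis) between the mean of the 2 miR-146a-5p libraries and scramble replicate 1 (circles) or scramble replicate 2 (squares), with the number of tested members beside each list. The NF-kB list lies at 0.97 and 1.21 and the interferon-stimulated list at 0.82 and 0.57, while the ribosomal protein list lies at 0.07 and -0.38.

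The seed of miR-146a-5p pairs with the heptamer AGTTCTC, and a transcript that carries it in the 3' UTR can be repressed directly. The 3' UTR of IRAK1 (ENSG00000184216) holds 2 matches of 8 bases, AGTTCTCA, on chromosome X from 154011812 to 154011819 and from 154011796 to 154011803 on the minus strand (GRCh38), within CGGAAGTCAAAGTTCTCATGGTCAGAAG and CATGGTCAGAAGTTCTCATGGTGCACGA. CARD10 has an 8-mer on chromosome 22 from 37490812 to 37490819 (TGCACACTCAAGTTCTCATGGGCAGGCT) and TIMM17B has 1 on chromosome X from 48893505 to 48893512 (ACATGTACGAAGTTCTCACCCCAGCTCC), both in the 3' UTR on the minus strand. TRAF6 carries 3 such 8-mers in its 3' UTR on chromosome 11, the most upstream from 36489358 to 36489365. Of the 6 genes that fell by DESeq2 and had an annotated 3' UTR, 5 carried a match, against 20.96% of the other tested genes (Fisher's exact test, two-sided p = 0.00201). Of the 41 that rose, 7 carried a match (Fisher's exact test, two-sided p = 0.701). Neither test takes account of 3' UTR length. STC1, a secreted glycoprotein hormone (4.44 ± 1.31 and 19.5 ± 1.45 CPM), and SIRPB1, a receptor of myeloid cells (10.95 ± 0.137 and 26.3 ± 1.08 CPM), rose although each has an 8-mer. EGFR, NUMB and SMAD4, which did not pass, also carry an 8-mer in the 3' UTR.

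Across all tested genes, the raw difference between those with and without a match changed with the correction for GC content and length. It lay below the median of permuted seeds both with and without that correction. Without it, the median log2 fold change of the 2594 genes with a match minus that of the 9765 genes without was 0.0043, and camera from limma called no shift of the set. With GC and length offsets, added after the data were seen, the difference was -0.08, against a median of -0.03 for permuted seeds (permutation p = 0.0143). Without offsets the difference was larger for most permuted seeds, with a median of 0.08, and 5 of 419 permuted seeds had one as low (two-sided permutation p = 0.0286). Against scramble replicate 1 alone, genes with an 8-mer had a median of -0.15 and genes with no match 0.03, and against scramble replicate 2 alone the medians were 0.20 and -0.06. Genes below both scramble libraries made up 23.7% of the 591 genes with an 8-mer and 17.2% of genes with no match. The difference from permuted seeds no longer passed with 8-mers only (permutation p = 0.0905), with all annotated 3' UTRs (0.0619), without scramble replicate 1 (0.119) or without scramble replicate 2 (0.262). With control genes matched on 3' UTR length, AU content and expression it was -0.05 (permutation p = 0.0286).

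**Figure D4:**
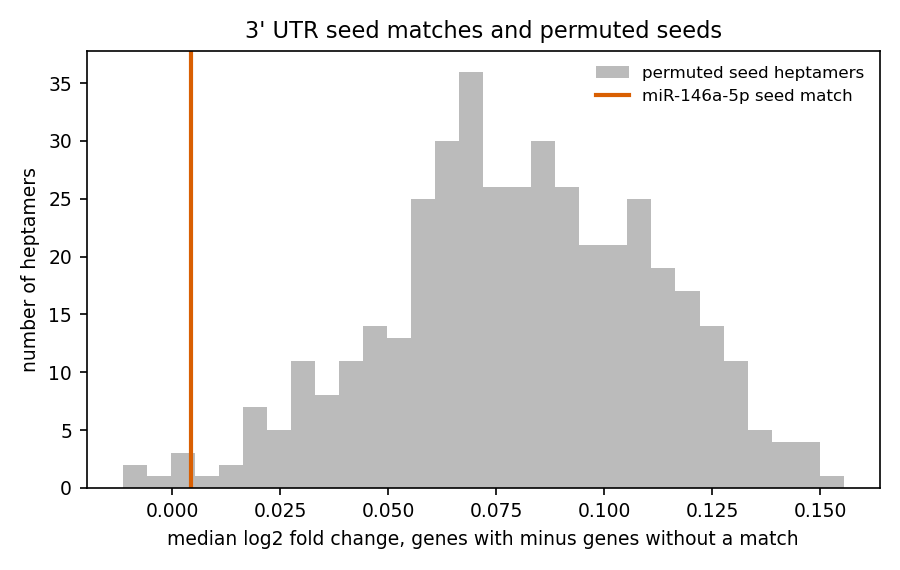
Histogram of the difference in median log2 fold change between genes with and without a 3' UTR match (horizontal axis) for 419 permuted seed heptamers (grey bars, number of heptamers), with the miR-146a-5p seed match as a line. The line lies at 0.0043, below the control median of 0.08, with 5 permuted seeds at or below it.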

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

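Tests of GC content and length, of GC-rich and GC-poor genes, quality weights, a crossed pairing, DESeq2 without each library, and permuted heptamers without CG were chosen only after the data were seen. The count of genes called was 0 with edgeR and stayed 0 with other scaling factors, with no filter or a stricter one, with stricter thresholds, with limma-voom (with and without quality weights), with GC and length offsets (1821 genes at p under 0.05, lowest adjusted p 0.125) and in GC-poor genes. It was 52 with DESeq2, 353 in GC-rich genes (218 higher, 135 lower, including all 28 of the DESeq2 genes among them), and between 8 and 8421 when a library was left out. DESeq2 called 5349 genes without scramble replicate 1, 1107 without scramble replicate 2 and 2 without either miR-146a-5p library. With 1 scramble library left, the spread comes from the miR-146a-5p pair alone (coefficient of variation 0.0612), which raises the count by construction; with 1 miR-146a-5p library left it comes from the scramble pair (0.478 and 0.477). The replicate numbers were not shown to pair the libraries (correlation of deviations -0.145): a replicate block called 5 genes, all higher (FN1, C3, CXCL1, CSF2 and CXCL8), and the crossed pairing called 0. Of the 65 named genes, 27 passed with DESeq2, 60 without scramble replicate 1, 53 without scramble replicate 2 and 6 without either miR-146a-5p library, none of them in the opposite direction. The 9 gene lists called by camera became 0 with an estimated correlation and 3 with fry, which tests each list alone. By fry the interferon-stimulated (adjusted p = 0.00314), basal urothelial (0.0303) and mesenchymal (0.0319) lists passed. The NF-kB (0.0629), G2/M (0.105) and mitochondrial (0.225) lists did not pass by fry. Camera called 9 lists with a replicate block, with DESeq2 size factors and with GC and length trends removed (8 of them shared). Leaving out a library gave between 5 and 9 lists, and the ribosomal protein list reversed without scramble replicate 2 (adjusted p = 0.118), while its adjusted p was 1.90e-05 without scramble replicate 1 and 0.262 without miR-146a-5p replicate 2. NF-kB, interferon-stimulated, G2/M and mitochondrial lists were called by camera at the preset correlation without each of the 4 libraries. The seed-match difference was 0.0043. It was 0.0212 with all annotated 3' UTRs and 0.0172 for 8-mers only, which no longer passed against permuted seeds, and between -0.11 and 0.16 when a library was left out. It still passed, below zero, with GC and length offsets (-0.08), matched genes (-0.05) and 7-mers only (-0.0016), and also with a mean of at least 10 CPM, the replicate block, and permuted heptamers without CG (0 of 299 as low, permutation p = 0.00667). The cause of these changes was not tested further. The spread between the 2 scramble libraries limits the calls. At the spread of all 4 libraries, given to both groups, edgeR recovered no simulated 4-fold change. Low counts add to the error of genes such as CD69, MUC5AC, CMPK2, KRT17 and BIK.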

Other observations

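Several genes called by DESeq2 belong to none of the lists and were named after their values were seen. NFKBIZ, an atypical NF-kB regulator, rose from 17.3 and 14.3 CPM to 80.0 and 79.9 CPM, ZC3H12A, a ribonuclease that degrades cytokine transcripts, from 5.82 and 10.2 CPM to 33.9 and 32.3 CPM, and CFB, complement factor B, from 3.04 and 4.13 CPM to 14.7 and 13.1 CPM. BTF3L4 and its processed pseudogene BTF3L4P2 rose by 1.34 and 2.08 log2 units, and these 2 share sequence, so their estimated counts cannot be taken as separate. Apart from these, SESN2, which is in the p53 target and stress response lists and was not called by DESeq2, stood out in a single library. It was listed at 0 CPM in scramble replicate 1 against 11.5, 12.8 and 8.72 CPM in the other libraries.

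The tests of scramble replicate 2 and of the NF-kB list below, and the test of chance among heptamers, were chosen only after the result was seen. The predictions for GGAGAACA and for sites outside the 3' UTR were written before those tests were run, once the GGAGAAC pattern had been seen. Scramble replicate 2 stood apart from the other 3 libraries. A model of transcript GC content and length, fitted on other genes, explained 63.0% of the variance of scramble 2 minus scramble 1 in held-out genes, against 4.46% for the miR-146a-5p pair, so a technical bias in which AU-rich transcripts were lost may account for much of it. A swap with a miR-146a-5p library is argued against by IRAK1, which was 6.595 times the miR-146a-5p mean in that library. Cells of another type are argued against by markers of fibroblasts, leukocytes and endothelium, which summed to 27.1 CPM there. RNA quality or a different library preparation stay open, since the labels give no batch.

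NF-kB response genes were higher in the miR-146a-5p libraries while IRAK1, which acts upstream of NF-kB, was lower. The composition of scramble replicate 2 is argued against by a median of 0.97 against scramble replicate 1 alone, and leukocytes by a ratio of 0.981 for their summed markers. A response to the transfected material that differs between the miR-146a-5p and scramble groups stays a candidate explanation, because 85.7% of tested interferon-stimulated genes also lay above both scramble libraries. The listed interferons themselves, IFNB1 and IFNL1, had at most 1 count in any library, so no rise of theirs was seen. An effect of miR-146a-5p itself is open too, and the design, with 1 miR-146a-5p and 1 control material, cannot separate the sequence from its preparation.

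A scan of all 3' UTR heptamers asked which motifs track the fold change once 3' UTR and transcript GC content, length and expression were regressed out. Of 16208 heptamers, AGTTCTC, the miR-146a-5p seed match, had the lowest z (-4.68, 1578 genes) and 16 of 1000 shuffles of genes had one as extreme, but shuffles treat genes as independent, and other heptamers reached z from -4.30 to 5.59 between the 2 scramble libraries. It was also the lowest against scramble replicate 1 alone (-4.44) but ranked 53 from the lowest against scramble replicate 2 alone. The mean shift was small, -0.04 log2 units. In the self-test, 5 of 5 heptamers given a shift of -0.1 came out lowest. That shift was larger than the one found, and simulated genes varied independently. The self-test therefore does not show whether a shift of -0.04 would be found.

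At the other end of that scan, genes with GGAGAAC in the 3' UTR were higher in the miR-146a-5p libraries (z 5.45, 1219 genes, mean 0.06), which was the highest z of all heptamers and the highest against scramble replicate 1 alone, but ranked 9 from the highest against scramble replicate 2 alone (z 3.54). Chance stays open, because 0 of 1000 shuffles of genes had a z that high but a heptamer unrelated to it reached 5.59 between the 2 scramble libraries. One candidate explanation, for a scramble RNA whose sequence is not given in the sources used here, is that it represses transcripts through a seed of its own, so that they appear higher with miR-146a-5p. Genes with the longer GGAGAACA exceeded other GGAGAAC genes by 0.0238 (permutation test, one-sided p = 0.156), which leaves that open. Their means were 0.0737 and 0.0465 against scramble replicate 1 alone, and closer together, 0.0617 and 0.0490, against scramble replicate 2 alone. Genes with GGAGAAC only outside the 3' UTR had a mean of 0.0197 ± 0.0075 (SE). A mean under 0.0288 had been set beforehand as the result against an effect outside the 3' UTR. The mean fell on that side, but with its SE it cannot be told from the bound, which leaves such an effect open as well. That mean also depended on the scramble library, at 0.0097 against scramble replicate 1 alone and 0.0332 against scramble replicate 2 alone.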
